A study of Methanothermobacter marburgensis with 6 samples.

How the data were processed

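Methanothermobacter marburgensis is a thermophilic archaeon that makes methane from hydrogen and carbon dioxide. Per the labels, a wild-type strain was grown without oxygen at 65 °C in a defined medium under a continuous flow of gas with 80% hydrogen, 20% carbon dioxide and 0.2% hydrogen sulfide. Nickel was set to 50 nM, which the labels call limiting, or to 5000 nM, which they call sufficient. Each level has 3 libraries, described as biological replicates, with total counts from 5121589 to 6991725 reads. Ribosomal RNA was depleted, and strand-specific libraries were sequenced as paired reads of 150 bases.

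The deposited table has 1875 rows: 1782 annotated genes and 93 unannotated transcripts, of which 35 carry small RNA identifiers. The authors' table gives a raw read count per row and library, as whole numbers. Deposited FPKM values stand beside them. The scaling constant of the FPKM, solved from the counts and lengths, lay between 0.928 and 1.26 times the column total, so its definition is not known, and FPKM entered no test. A further deposited signal per library is the count divided by a size factor. These normalised counts equal the counts divided by median-of-ratios size factors over all rows, within 4.92e-05 reads. The authors also deposited a log2 fold change, a p-value and an adjusted p-value per row, with no value in 5 rows that hold at most 1 read each. DESeq2 is named per the submitters' processing notes, without a version. The aligner, the read counter, its strand setting and the genome build are not given in the sources used here. Positions are those of the deposited table, which places all rows on 1 sequence under a placeholder name.

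The tests, the gene lists, the rule for named genes and the alternatives, except where stated, were chosen before the data were examined. The planned test was limma on log2 values, with edgeR in its place if the values proved to be raw counts. They did, so edgeR 4.0.16 in R 4.3.3 was the main test: TMM scaling, glmQLFit and glmQLFTest with nickel level as the only term, coded as 50 nM minus 5000 nM. Rows with a mean normalised count of at least 10 over the 6 libraries were tested, 1825 in all. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the root of edgeR's F statistic. Levels are the authors' normalised counts, as mean ± SD of 3 libraries.

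The 33 gene lists were symbol and product patterns. Unannotated transcripts were left out of them, since they carry the product text of the gene on the other strand. Lists with at least 3 tested members, 29 of them, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes. The patterns matched imperfectly. The table gives the subunits of the second methyl-coenzyme M reductase the same symbols as those of the first, so both fell in the list for isoenzyme I and the list for isoenzyme II stayed empty. The Frh list took in 3 proteins that share only a domain with FrhB, and the Hyp list took in frhD. The Hmd list held hmd, hmdB and hmdC, while the proteins related to Hmd fell in the C1 list. The phosphate list took in thiamine pyrophosphate-binding proteins. The patterns took in 2 of the 18 genes of the Eha locus and 3 of the 16 of the Ehb locus. For this reason 7 loci were defined by annotation and position after the data were seen, and tested as a family of their own. The gene mtd has no symbol in the table and was taken by its product name.

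Ratios between families were formed within a library as log2 of summed normalised counts and compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1, so Benjamini-Hochberg adjustment over the 4 ratios leaves it at that value. Named genes follow a rule: the 10 largest increases and the 10 largest decreases among rows past the threshold, with separate groups and a mean of at least 50 normalised reads; all tested members of the Frh, Mvh, Hmd, Mcr and Hdr lists and mtd; and the 4 members with the smallest p of each other list. Genes outside the rule were chosen after their values were seen.

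Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom between 24.1 and 84.4, so no library was a copy of another. The biological coefficient of variation in edgeR was 10.9%. The procedure was tested on simulated counts of 1825 rows built from these libraries for the comparison of 50 nM with 5000 nM, with 200 rows changed. It recovered 91.0% of rows changed 1.5-fold, 97.0% of those changed 2-fold and 66 of 66 of those changed 4-fold. Of its 200 calls, 8 were unchanged rows. The simulated rows varied independently, with changes of at most 4-fold, as many higher as lower. These rates therefore do not cover larger changes or a shift in totals from abundant genes. Transcripts opposite a gene were compared with it where the overlap was at least 50% of the transcript, with at least 50 gene reads and 5 opposite-strand reads in each library. Alternatives covered the filter, the scaling, limma, DESeq2 1.42.0, pseudocounts, stricter thresholds, the replicate number as a block and each library left out in turn. Pseudocounts apply only to limma, so they were changed within that alternative. Figures were drawn with matplotlib 3.10.9, and ratios were tested with scipy 1.17.1.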

Results

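Gene expression of Methanothermobacter marburgensis was compared between cultures with 50 nM and 5000 nM nickel, 3 libraries each. The study's stated interest was how the hydrogenases of methanogenesis respond to nickel. Total counts ran from 5121589 to 6991725 reads per library, and rRNA and tRNA rows held at most 0.0205% of them. The first principal component held 90.8% of the variance and separated the nickel levels. Pearson correlations of log2 values across genes were at least 0.989 within a level and at most 0.895 between levels.

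At 50 nM nickel the genes of the F420-reducing hydrogenase Frh fell, frhA 23.2-fold, while the genes of the nickel-free hydrogenase Hmd rose, hmd 6.19-fold. An FmdE family gene (MTBMA_RS05175) and a CobN-type chelatase gene (MTBMA_RS03375) rose 130-fold and 144-fold. Transporter genes annotated for cobalt or nickel uptake went both ways. By edgeR's quasi-likelihood test 752 of the 1825 rows passed the adjusted threshold, 377 higher and 375 lower at 50 nM, and 163 of them changed at least 2-fold, 111 higher and 52 lower. The split depends on scaling: with libraries set to equal totals, which puts the median log2 fold change of all genes at -0.31 instead of 0.0068, it was 163 higher and 935 lower, and with quantile normalisation in limma 270 higher and 527 lower. With equal totals after 6 genes that rose and held at least 1% of reads at 50 nM were left out it was 390 higher and 274 lower, and after all 15 genes with at least 1% of reads on average were left out, whichever way they changed, 284 higher and 413 lower, both settings chosen after the data were seen. In 961 rows (52.7%) the 3 libraries of one level all lay above the 3 of the other, against 10% by chance. The authors' deposited table calls 750 rows at the same threshold, and 727 rows were called in both.

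**Figure D1:**
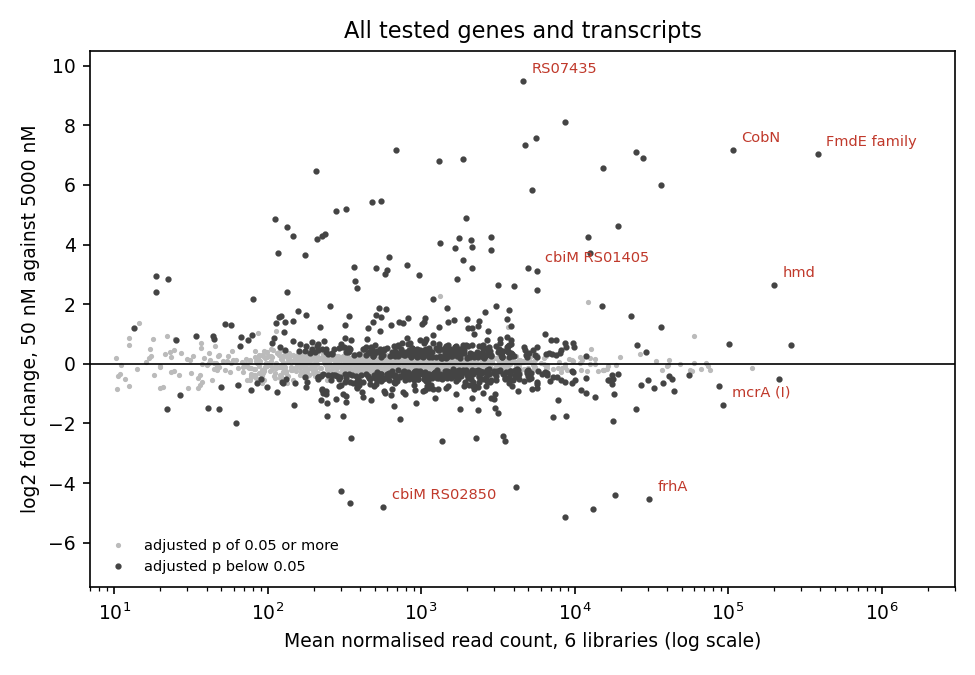
Mean normalised read count over the 6 libraries (horizontal, log scale) against the log2 fold change at 50 nM relative to 5000 nM nickel (vertical) for each tested row, dark where the adjusted p of edgeR was below 0.05. The FmdE family gene stands at 7.02 and frhA at -4.54.

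All 4 genes of the frh operon (positions 1536012 to 1539396) fell. This enzyme is a nickel-iron hydrogenase that reduces coenzyme F420. The alpha subunit gene frhA stood at 2526 ± 239 normalised reads at 50 nM and 58893 ± 5611 at 5000 nM (SD, n = 3), 23.2-fold lower (log2 fold change -4.54, SE 0.13, adjusted p = 7.99e-10 by edgeR). The log2 fold changes of frhB, frhG and frhD were -4.39, -4.88 and -5.14. Of the 7 tested members of the Frh list, 4 fell, 1 rose and 2 did not pass, the same counts as adjusted over the list alone. The member that rose, MTBMA_RS07425, is a beta-domain protein encoded near hmdC, and MTBMA_RS03585 and MTBMA_RS03170, at -0.08 and 0.06, did not pass, though MTBMA_RS03585 did with equal totals (-0.41). The camera test of the Frh list gave an adjusted p = 7.25e-05, and an adjusted p = 0.491 with an estimated correlation. For the frh operon, a set defined after the data were seen, these were 2.21e-17 and 0.0332.

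The gene hmd, which encodes the [Fe]-hydrogenase, an enzyme that contains no nickel, rose 6.19-fold, from 55741 ± 913 to 344004 ± 24881 normalised reads (SD, n = 3, log2 fold change 2.63, SE 0.12, adjusted p = 3.49e-08 by edgeR). It took 5.23% of all reads at 50 nM and 1.06% at 5000 nM. The genes hmdB and hmdC, annotated for synthesis of the enzyme's cofactor, rose by 1.94 and 3.73 on the log2 scale. All 3 members of the Hmd list rose, also when adjusted over the list alone (camera adjusted p = 2.41e-05, and adjusted p = 0.491 with an estimated correlation). The single tested member of the Hcg list, MTBMA_RS07465, rose by 1.34. In the run from hmd to MTBMA_RS07470, which includes that gene (positions 1407435 to 1412890), defined after the data were seen, all 7 genes rose, with a median log2 fold change of 1.74 (adjusted p = 5.12e-09, and 0.0332 with an estimated correlation). On the other strand beside hmd, MTBMA_RS07435, a hypothetical protein, MTBMA_RS07430, a molybdopterin-dependent oxidoreductase, and MTBMA_RS07425 rose by 9.48, 8.11 and 7.56, from 12.7 ± 3.10, 62.6 ± 9.04 and 58.7 ± 7.46 normalised reads at 5000 nM (SD, n = 3). The Hmd-related gene MTBMA_RS00475 fell by 0.88 on the log2 scale, and its relative MTBMA_RS04380, at -0.24, did not pass, though it did with equal totals (-0.57) and without replicate 3 of 5000 nM (-0.33). The latter was chosen after its value was seen. The gene for the F420-dependent dehydrogenase Mtd (MTBMA_RS00250), which acts on the same substrate as Hmd, stood at 43146 ± 3622 normalised reads at 50 nM and 39823 ± 1679 at 5000 nM (SD, n = 3) and did not pass (log2 fold change 0.12, SE 0.10, adjusted p = 0.388 by edgeR), nor with equal totals, where its sign was the opposite (-0.20).

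**Figure D2:**
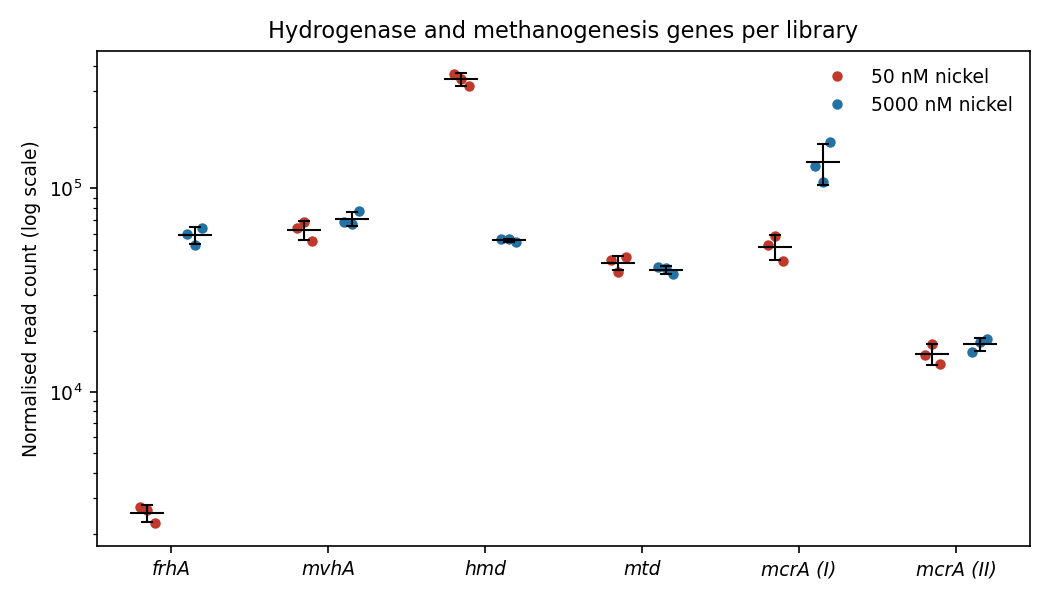
Normalised read counts (vertical, log scale) of frhA, mvhA, hmd, mtd (MTBMA_RS00250) and both mcrA genes in each library, red for 50 nM and blue for 5000 nM nickel, with bars for the mean and SD of 3 libraries; I and II mark the isoenzymes of methyl-coenzyme M reductase. The mean of hmd is 344004 at 50 nM and 55741 at 5000 nM, and that of frhA is 2526 and 58893.

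The F420-non-reducing hydrogenase Mvh, a nickel-iron enzyme that works with heterodisulfide reductase, had 1 of 3 listed genes past the threshold. Of its 3 listed genes, mvhG fell by 0.42 on the log2 scale (SE 0.11, adjusted p = 0.0126 by edgeR), and mvhA at -0.18 and mvhB at 0.02 did not pass. With equal totals both did, at -0.50 and -0.30, and mvhA did with quantile normalisation, at -0.25. Adjusted over the list alone, 1 gene passed. The list gave a camera adjusted p = 0.842. The adjoining gene of the operon, MTBMA_RS07410, chosen after its value was seen, fell by 0.54 and passed (adjusted p = 0.00117 by edgeR). The operon thus had 2 of 4 genes past the threshold, and gave a camera adjusted p = 0.432. MTBMA_RS07420, with the product name of MTBMA_RS07410 but outside the operon, rose by 6.79 (adjusted p = 5.04e-10 by edgeR). It stood at 23.9 ± 8.07 normalised reads at 5000 nM (SD, n = 3) and was also chosen after its value was seen. All 3 heterodisulfide reductase genes fell: hdrA stood at -0.74, hdrC at -0.72 and hdrB at -0.63 on the log2 scale, also when adjusted over the list alone, and the list gave a camera adjusted p = 0.235, though 0.0204 with limma, and an adjusted p = 0.783 with an estimated correlation. The energy-converting hydrogenases Eha and Ehb, membrane enzymes that use nickel, fell as whole loci. Both tested members of the Eha list and all 3 of the Ehb list fell, also when adjusted over the list alone, and the Ehb list gave an adjusted p = 0.0390 by camera and an adjusted p = 0.491 with an estimated correlation. That call was lost without replicate 2 of 50 nM (adjusted p = 0.0678 by camera). In the Eha locus (positions 714291 to 724992) all 18 genes fell, with a median log2 fold change of -0.73 (adjusted p = 1.71e-05, and 0.0332 with an estimated correlation). In the Ehb locus (positions 1493845 to 1502903) all 16 fell, with a median of -1.09 (adjusted p = 3.44e-07, and 0.0581 with an estimated correlation). Both loci were defined after the data were seen.

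**Figure D3:**
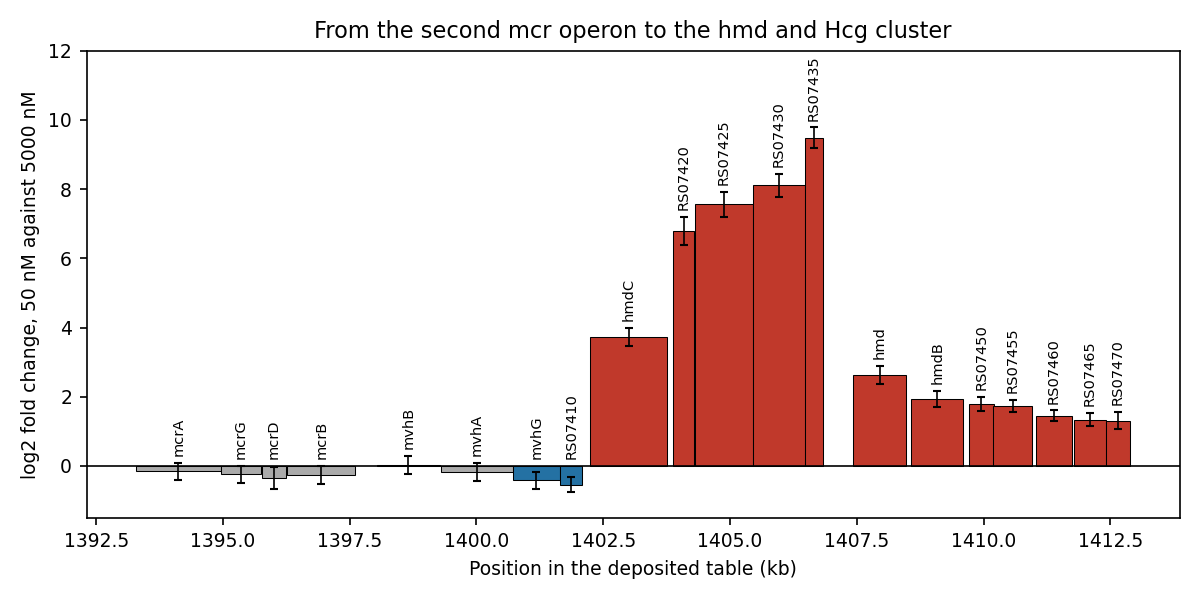
Log2 fold change at 50 nM relative to 5000 nM nickel (vertical) of each gene from the mcr operon of isoenzyme II to the end of the hmd and Hcg cluster, at its position in the deposited table (horizontal, kb), with 95% confidence intervals; red bars passed the threshold and were higher, blue passed and were lower, grey did not pass. The bars of mvhB at 0.02, which is negative with equal totals (-0.30), and MTBMA_RS07435 at 9.48 are the lowest and highest in size.

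Ratios within a library do not depend on the scaling between libraries. The log2 ratio of hmd to the summed Frh list was 4.30 ± 0.14 at 50 nM and -1.29 ± 0.17 at 5000 nM (SD, n = 3, exact permutation p = 0.1, the smallest this design allows). That of hmd to mtd was 3.00 ± 0.18 and 0.49 ± 0.04, and that of the Frh list to the Mvh list -3.18 ± 0.05 and -0.38 ± 0.08, with the same exact p. The Frh list holds MTBMA_RS07425, which rose, so the change in hmd to Frh grows from 5.60 to 7.25 when the frh operon alone is used. The ratio of the mcr operon of isoenzyme II (Mrt) to that of isoenzyme I was -1.44 ± 0.06 and -2.70 ± 0.24 (exact permutation p = 0.1).

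Methyl-coenzyme M reductase, the enzyme of the last step of methane formation, carries a nickel cofactor and has 2 isoenzymes here. The operon of isoenzyme I fell: mcrA (MTBMA_RS07550) stood at 51723 ± 7336 normalised reads at 50 nM and 134774 ± 31235 at 5000 nM (SD, n = 3, log2 fold change -1.38, SE 0.18, adjusted p = 1.59e-04 by edgeR), and mcrG (MTBMA_RS07555) fell by 1.93. The 4 genes of isoenzyme II lay between -0.34 and -0.16 and did not pass by edgeR, DESeq2 or limma, with 1 below an unadjusted p of 0.05. With equal totals all 4 passed as lower, with mcrA (MTBMA_RS07375) at -0.49, and with quantile normalisation mcrD (MTBMA_RS07385) and mcrB (MTBMA_RS07390) did, at -0.42 and -0.43. The mcrD of isoenzyme II also passed without replicate 2 of 50 nM (-0.47). Together 5 of 9 listed genes fell, also when adjusted over the list alone (camera adjusted p = 0.0126, and adjusted p = 0.779 with an estimated correlation). The 2 mcrA genes are related in sequence, and how reads common to both were counted is not given in the sources used here. The operons alone gave adjusted p = 4.86e-04 for isoenzyme I, 0.235 with an estimated correlation, and 0.432 for isoenzyme II. Of the Mtr methyltransferase list 8 of 9 genes fell, among them mtrC at -1.21 and mtrG at -1.18, and 9 when adjusted over the list alone (camera adjusted p = 0.0230, and adjusted p = 0.779 with an estimated correlation). Of the list for the earlier C1 steps, which took in the Hmd-related proteins, 8 of 12 genes fell, the Hmd-related MTBMA_RS00475 among them. Led by mer at -0.91, 10 fell when adjusted over the list alone, and 5 and 4 without replicate 2 and 3 of 50 nM. The list gave a camera adjusted p = 0.124, 0.00426 with limma, and an adjusted p = 0.772 with an estimated correlation. Of the carbon monoxide dehydrogenase and acetyl-CoA synthase list, also a nickel enzyme, 5 of 7 fell, also when adjusted over the list alone, among them cdhA at -1.56 and acsC at -1.64 (camera adjusted p = 1.22e-04, and adjusted p = 0.491 with an estimated correlation). All 9 ATP synthase genes fell, with a median of -0.54, also when adjusted over the list alone (camera adjusted p = 0.0575). That list passed without replicate 1 of 50 nM (0.0410) or of 5000 nM (0.0112), with equal totals (0.0452) and with limma (7.30e-04), and had an adjusted p = 0.783 with an estimated correlation.

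Of the 9 tested members of the nickel uptake and regulation list 6 rose and 3 fell, also when adjusted over the list alone. One transporter locus rose, with cbiM (MTBMA_RS01405) 8.69-fold higher at 10225 ± 338 normalised reads at 50 nM and 1180.4 ± 109.6 at 5000 nM (SD, n = 3), while another fell, with cbiM (MTBMA_RS02850) 28.0-fold lower at 38.8 ± 2.35 normalised reads at 50 nM and 1097 ± 72.4 at 5000 nM and cbiQ (MTBMA_RS02860) at a log2 fold change of -4.67. The transporter permease gene MTBMA_RS03200 rose by 3.89. The genes annotated as the nickel-responsive regulator NikR, chosen after their values were seen, rose by 4.04 (MTBMA_RS03605) and 1.22 (MTBMA_RS05530). The list gave a camera adjusted p = 0.0246, and an adjusted p = 0.491 with an estimated correlation. That call was lost with equal totals (camera adjusted p = 0.0514), with limma (0.0612) and without replicate 1 (0.0543) or replicate 2 (0.0694) of 5000 nM. Of the hydrogenase maturation list 1 rose (hycI, by 1.21) and 1 fell (frhD), the same counts as adjusted over the list alone, and hypA, hypB, hypD, hypE and hypF did not pass, of which hypB (MTBMA_RS05745) and hypE (MTBMA_RS03225) did with equal totals, at -0.57 and -0.45, and hypB did without replicate 3 of 50 nM, at -0.34, and with quantile normalisation, at -0.33 (camera adjusted p = 0.250). Of the 5 genes for coenzyme F430, the nickel cofactor, cfbD (MTBMA_RS00515) rose by 0.52, a call lost with equal totals (0.20), and the others did not pass, also when adjusted over the list alone (camera adjusted p = 0.872). With equal totals cfbA (MTBMA_RS08710) and cfbB (MTBMA_RS00230) passed as lower, at -0.38 and -0.26. All 4 iron transport genes fell, with feoB (MTBMA_RS08555) at -1.42, also when adjusted over the list alone (camera adjusted p = 0.0609, and 0.0256 without replicate 2 of 5000 nM 0.0104 with limma, and adjusted p = 0.779 with an estimated correlation). The other feoB (MTBMA_RS03260), at -0.44, did not pass without replicate 1 or 3 of either level (-0.36 and -0.42 without those of 50 nM, -0.36 and -0.38 without those of 5000 nM), nor with limma without its trend (-0.43).

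Outside these groups, the largest increases by the naming rule included the FmdE family gene MTBMA_RS05175, at 759702 ± 66417 normalised reads at 50 nM and 5859 ± 825 at 5000 nM (SD, n = 3, 130-fold, adjusted p = 5.04e-10 by edgeR). It took 11.5% of all reads at 50 nM and 0.111% at 5000 nM. The CobN-type chelatase gene MTBMA_RS03375 rose 144-fold and the C39 peptidase domain gene MTBMA_RS00245 144-fold. At 5000 nM MTBMA_RS00245 stood at 3.50 ± 1.60 FPKM and MTBMA_RS03375 at 59.6 ± 7.32 (SD, n = 3), so the fold of MTBMA_RS00245 rests on a low and variable level. The regulator gene MTBMA_RS05285 rose 119-fold and the hypothetical gene MTBMA_RS04095 117-fold. Among the largest decreases were MTBMA_RS04445 and MTBMA_RS04450, without assigned function, at -2.60 and -2.60. The transporter component MTBMA_RS02855, also among them at -4.26, belongs to the falling transporter locus given above, with cbiM (MTBMA_RS02850) and cbiQ (MTBMA_RS02860). Of the 20 rows, 3 were unannotated transcripts opposite frh genes, MTBMA_RS05175 and MTBMA_RS03375, at -4.15, 7.09 and 7.34. How strand entered the counting is not given in the sources used here, nor is how reads common to related genes, such as the CobN genes, were assigned.

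Of the ribosomal protein genes 34 of 60 fell, 36 when adjusted over the list alone, with a median of -0.29, and 21 without replicate 3 of 50 nM (camera adjusted p = 0.0145, and adjusted p = 0.779 with an estimated correlation). Of the chromatin proteins 4 of 5 rose, led by albA at 1.22, also when adjusted over the list alone (camera adjusted p = 0.251, 0.0156 with limma, and adjusted p = 0.783 with an estimated correlation). The histone gene MTBMA_RS03465, at 0.30, stood at -0.02 with equal totals, and its call was lost without replicate 1 (0.29) or 3 (0.22) of 50 nM and 2 (0.28) or 3 (0.23) of 5000 nM, with limma without its trend (0.29) and with quantile normalisation (0.16). Of the cell envelope list 6 rose and 4 fell, the same when adjusted over the list alone, with the pseudomurein-binding repeat genes MTBMA_RS07745 at 3.20 and MTBMA_RS02920 at -0.89, and 2 fell without replicate 1 of 5000 nM (camera adjusted p = 0.837).

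Of the redox defence list, the thioredoxin MTBMA_RS05870 and the rubredoxin MTBMA_RS02980 stood at 0.68 and 0.61. That list had 6 higher and 1 lower of 16, phosphate transport 7 higher of 12, 3 of them thiamine pyrophosphate-binding proteins, cobalamin synthesis 4 higher of 15, with cbiD at 0.77, and other metal transport 3 higher and 1 lower of 11, each the same when adjusted over the list alone. Cofactor synthesis had 2 higher and 2 lower of 15, mobile elements 2 and 2 of 10, chaperones and proteolysis 2 and 1 of 16, RNA polymerase 2 and 3 of 15, and iron-sulfur assembly 1 lower of 3, also the same when adjusted over the list alone. Aminoacyl-tRNA synthetases had 1 higher and 5 lower of 18, 1 and 4 adjusted over the list alone. The list of rRNA and tRNA genes and of enzymes that act on tRNA had 9 higher and 3 lower of 35, 8 and 3 adjusted over the list alone, with the tRNA genes MTBMA_RS06990 and MTBMA_RS06995 at 2.42 and 1.43. The level of MTBMA_RS06990 was low and variable, at 67.9 ± 21.1 FPKM at 50 nM and 12.3 ± 0.97 at 5000 nM (SD, n = 3). All rRNA and tRNA rows together held at most 0.0205% of a library's reads. None of the 10 nitrogen assimilation genes passed by edgeR, also when adjusted over the list alone, with 0 below an unadjusted p of 0.05 and 0 called by DESeq2 or limma. With equal totals glnA (MTBMA_RS00770), the nitrogenase component gene MTBMA_RS00320 and the ammonium transporter gene MTBMA_RS05100 passed as lower, at -0.47, -0.48 and -1.11, and glnA did with quantile normalisation, at -0.25. The CRISPR-associated gene MTBMA_RS04435, at 0.25, did not pass but did when adjusted over the list alone, without unannotated rows (0.26) and without replicate 2 of 50 nM (0.35) or of 5000 nM (0.30). Several of these counts of list members changed when 1 library was left out. Leaving out 1 library also lowered the count of all called rows, from 752 to between 618 and 676. The single lower call of the redox defence list was lost without replicate 1 or 3 of 50 nM or replicate 2 of 5000 nM, and 4 members were higher without replicate 1 of 50 nM. The phosphate transport list had 4 higher without replicate 3 of 50 nM and 3 without replicate 1 of 5000 nM. Other metal transport had 2 higher and 2 lower, and cobalamin synthesis 1 lower, without replicate 3 of 5000 nM. Among mobile elements both lower calls were lost without replicate 1 or 2 of 50 nM and 1 of them without replicate 1 or 2 of 5000 nM, and 1 higher call was lost without replicate 1 or 3 of either level. The iron-sulfur assembly call, MTBMA_RS07480 at -0.41, was lost without replicate 2 (-0.36) or 3 (-0.35) of 50 nM and with limma without its trend (-0.41). RNA polymerase had 1 lower without replicate 2 of 50 nM, and chaperones 2 lower without replicate 1 or 3 of 50 nM. Aminoacyl-tRNA synthetases had 2 lower without replicate 1 of either level and 3 without replicate 2 or 3 of 50 nM, and the rRNA and tRNA list had 1 lower without replicate 1 of 50 nM. For RNA polymerase, chaperones, mobile elements and nitrogen assimilation the median, the mean and the camera direction differed in sign. The lists from redox defence to nitrogen assimilation had camera adjusted p-values of at least 0.766.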

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

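The tests with the deposited size factors, without unannotated rows, with equal totals without abundant genes, with limma at a pseudocount of 1 and on operons by position, and the hydrogenase count at stricter thresholds, were chosen after the data were seen. The count of 752 changed rows was 748 without a filter, 742 with a minimum of 50, 748 with DESeq2, 742 with limma at each of 3 pseudocounts, 695 without its trend and 797 with quantile normalisation. It ranged from 618 to 676 when 1 library was left out. A minimum change of 2-fold gave 163 (111 higher, 52 lower), and an adjusted p below 0.01 gave 498, with 235 lower, as stricter thresholds must. Equal totals gave 1098 rows, 163 higher and 935 lower, with the median of all genes at -0.31, and 538 of the rows were shared with the main test. There MTBMA_RS00930 and MTBMA_RS03465, higher in the main test, stood at -0.0052 and -0.017 and did not pass, 15 more named genes lost the call and 17 gained it, and the cause follows from the shift of the median. With quantile normalisation the hypothetical gene MTBMA_RS04980, higher in the main test, was called lower at -0.26. That scaling sets values by rank, and this gene stood above MTBMA_RS05175 and hmd at 5000 nM and below both at 50 nM. Its lower value there follows by construction from a lower rank at 50 nM. Whether MTBMA_RS05175 and hmd alone account for that rank was not tested.

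The replicate number as a block gave 557 rows, 556 of them also called without it. No pairing by equal numbers was seen: deviations of same-numbered libraries from their group means correlated at -0.43 to -0.07. Of the 6 libraries, 0 correlated best with its own number. The labels do not say what equal numbers share, so these values cannot exclude a pairing. The block changed no list's call, and 10 named genes lost theirs, mvhG among them.

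The 8 lists past the threshold became 0 with an estimated correlation, with 1 below an unadjusted p of 0.05, and 21 with fry, which asks whether a list's genes move, on balance, one way and does not set them against other genes. Correlation between genes does not account for the first change in every list. The Ehb list, with an estimated correlation of -0.352, went from an unadjusted p = 0.0108 to 0.0614 by camera. The cause was not tested further. Without 1 library the number of lists past the threshold was 7 to 9. Of the loci, the calls for Frh, Eha and the hmd and Hcg cluster held with an estimated correlation, and those for Ehb and isoenzyme I of methyl-coenzyme M reductase did not (0.0581 and 0.235). With limma the Hdr, C1, iron transport, ATP synthase and chromatin lists passed and the nickel list did not, and the cause was not tested. The count of 14 changed genes in the Frh, Mvh, Eha, Ehb and Hmd lists lay between 13 and 17 under the other filters, scalings, tools, the block and each library left out. It was 10 with a minimum change of 2-fold and 13 at an adjusted p below 0.01. The change in the log2 ratio of hmd to Frh was 5.60, and 4.26 with geometric means, 7.17 with frhA alone and 7.25 with the operon. That of Frh to Mvh was -2.80, and -1.44, -4.36 and -4.42 in the same order. No direction of a ratio changed. These alternatives differ by construction in which Frh list members enter and how they are averaged.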

Other observations

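The tests of opposite-strand transcripts and of abundant genes were chosen only after the result was seen, and those of neighbouring genes and of other splits, planned earlier, had their bounds set after it. Genes outside the naming rule in the next sentences were chosen after their values were seen. Beside the FmdE family gene, MTBMA_RS05160 and MTBMA_RS05165, annotated as CobN-type chelatase subunits, and the hypothetical gene MTBMA_RS05170 rose 24.8-fold, 64.1-fold and 94.4-fold. A run from MTBMA_RS08455, a C39 family peptidase gene, to MTBMA_RS08475 rose by 1.94 to 4.24, and the hypothetical genes MTBMA_RS08720, MTBMA_RS08725 and MTBMA_RS08730 rose by 4.90, 5.18 and 5.13. The neighbours of MTBMA_RS04445 and MTBMA_RS04450, MTBMA_RS04440 and MTBMA_RS04455, stood at -2.50 and -2.50, and the DUF371 gene MTBMA_RS05000 at -2.44. The cdhB copy MTBMA_RS06935, away from the other cdh genes, stood at 0.04 and did not pass by edgeR.

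Among adjacent genes on 1 strand that both passed, 331 of 356 pairs (93.0%) changed in the same direction, against 60.3% of 68 adjacent pairs on opposite strands. Shuffling the directions among changed genes 10000 times gave at most 59.6% for the first (permutation p = 0.0001, the smallest these shuffles can give). Transcription of neighbouring genes together may account for this, and regulation of neighbouring operons by 1 factor was not tested apart from it.

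Log2 fold changes of unannotated transcripts lay within 0.5 of those of the genes they lie opposite to in 83 of 87 pairs. In 32 pairs the transcript passed the threshold, in some opposite a gene near 0, such as sRNA00025 at 0.32 against -0.04. In these 87 pairs the opposite strand held a median of 9.79% of the gene's reads (quartiles 6.92% and 14.9%). This share moved together from library to library. The mean correlation between pairs of its deviations from the group means was 0.78, against at most 0.05 in 1000 shuffles within groups. The median share per library ran from 7.48% in replicate 2 at 5000 nM to 13.4% in replicate 2 at 50 nM. Reads of the annotated gene assigned to the opposite strand are a candidate explanation. The fold change of the transcript exceeded that of the gene in 84 of the pairs, by a median log2 difference of 0.28, so the offset was largely common to them. For the 32 transcripts that changed, the median absolute difference less their median offset of 0.26 was 0.11 (bootstrap interval 0.058 to 0.17). Their genes had a median absolute log2 fold change of 1.20. Beyond the common offset, this argues against these transcripts, as a set, changing apart from the gene. A median does not speak for single pairs. With the offset left in, the median absolute difference was 0.28 over all pairs, close to the bound of 0.3. Transcripts of their own that change as the gene does stay open, and some pairs stood apart: sRNA00020 and sRNA00048 held 202% and 57.9% of their genes' reads, and the differences from the gene ran from -0.52 for sRNA00008 to 0.59 for the transcript opposite MTBMA_RS01270.

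The shift of the median under equal totals may come from a few genes that take many reads at 50 nM. The 6 genes that rose in the main test and held at least 1% of reads there included the FmdE family gene, hmd, MTBMA_RS04980 and MTBMA_RS04985. They took 27.7% of reads at 50 nM and 6.56% at 5000 nM. With quantile normalisation MTBMA_RS04980 was lower and MTBMA_RS04985, at 0.020, did not pass. Genes picked because they rose must raise the median when left out, so the test left out all 15 genes with at least 1% of reads on average, of which 5 rose and 3 fell. The median log2 fold change of the others was then -0.0507, against -0.31 with all genes in. These 15 genes held 39.0% of reads at 50 nM and 26.8% at 5000 nM, so leaving them out must raise the median too. The values give the size of that effect and cannot tell it from other causes of the shift. A change in total mRNA per cell cannot be read from these counts and stays untested.

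The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 752 rows by edgeR, with 896 below an unadjusted p of 0.05. The highest of the others called 0, with at most 53 below that unadjusted p. So 1 split, the real one, gave as many. Every other split mixes both nickel levels in each of its groups. The nickel difference then enters the residual spread, and few calls follow by construction. The comparison therefore cannot decide whether the calls arose by chance. For gene lists with camera's preset correlation the real split called 8 and the highest other 10. So 2 splits, the real one included, gave at least as many. The mixed splits keep part of the nickel difference, so their list counts do not give a chance level either.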
